A study of Homo sapiens with 6 samples.

How the data were processed

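RNA was sequenced in 6 libraries of HFF human foreskin fibroblasts, an established culture from a cell bank, irradiated with 40 mJ per cm2 of UVB and kept for 48 h with vehicle or with 10 µM sauchinone, 3 libraries in each group. Per the labels' protocols, the compound was added directly after irradiation, and a further version added it before irradiation as well. The labels do not say which version the libraries came from. Per the labels' protocols, total RNA was enriched by poly(A) selection or, alternatively, by removal of ribosomal RNA, without saying which was used for these libraries, and strand-specific paired-end libraries were made by the dUTP method. Poly(A) selection removes most RNA without a tail. Removal of ribosomal RNA keeps such RNA where it is not ribosomal, so the choice affects levels of histone RNA. Whether mitochondrial ribosomal RNA was removed is not stated.

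The authors deposited a table of 61806 genes with raw counts per gene and library, FPKM values and the exonic size of each gene. Reads were placed on GRCh38, per the submitters' processing notes. The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here. Because the use of strand is not stated, genes that overlap an antisense partner are uncertain. The counts are whole numbers that were not normalised by the authors. The deposited FPKM values equalled the count scaled by exonic size and total count in 100% of values in each library, within 0.006, so they hold no further information and were not tested. Gene names, coordinates and Gene Ontology terms are those of the deposited table. Every row names a gene, no column belongs to another sample, and columns were matched to samples by the column names that the labels give.

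Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15704 genes), libraries were scaled by TMM, and the quasi-likelihood test compared UVB + sauchinone with UVB without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Positive log2 fold changes mean higher with sauchinone. Standard errors were taken from the fold change and its F statistic. CPM values are counts scaled to TMM-adjusted library sizes. Total counts of 20984851 to 23076388 gave a median standard error of 0.12 for the log2 fold change. The 95% interval of a ratio of low counts is an exact binomial interval and covers counting error only.

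The 27 gene lists (19 on biology and 8 controls for other cell types and RNA quality) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 27 lists. Named genes followed a rule: the 6 largest rises and falls among named genes with an adjusted p under 0.05, a mean of at least 1 CPM before TMM scaling and no overlap between the groups, the 2 members of each biological list with the smallest p, and MMP1, COL1A1, CDKN1A, IL6, LMNB1 and HMOX1 whatever their p. Other genes are named only where a count is small or a closing observation needs them, after their values were seen. A few genes that the rule or a small count would name are not reported here. The groups, tests, lists, naming rule and alternatives were set before the data were examined.

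The alternatives set beforehand were DESeq2 1.42.0, other normalizations, other filters on low counts, limma-voom, a minimum fold change, the replicate number as a block, each library left out in turn, an estimated correlation in camera, and fry. A pseudocount alternative did not apply, since the table holds counts. Chosen after seeing the data were per-library offsets that remove a smooth trend of counts with genomic span, exonic size or transcript GC content, comparison of each list with 10000 random lists matched on span and mean expression, Gene Ontology enrichment, a list of RNAs without a poly(A) tail and a list of abundant fibroblast genes. GC content came from GENCODE release 29 transcripts on GRCh38, which gave a value for 98.2% of tested genes. Gene Ontology enrichment used a one-sided Fisher's exact test on genes changed at least 2-fold, against the 12004 tested genes with a biological process term, over 1921 terms of 10 to 300 genes.

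The test was tested on simulated data with the real means and library sizes of the 15704 genes, of which 200 were changed. It recovered 37 of 67 genes changed 1.5-fold (55.2%), 56 of 67 changed 2-fold (83.6%) and 63 of 66 changed 4-fold (95.5%), and 8 of its 164 calls (4.88%) were false. Far fewer genes were changed in this simulation than the 7786 called in the real data, so these rates need not hold there. Camera called a list shifted by 0.5 on the log2 scale in 20 of 20 simulations and called 1 of 520 unchanged lists. Genes were drawn independently in these simulations, so they do not test the preset correlation of 0.01. Estimated correlations in the real lists ran from −0.139 (endothelial markers) to 0.787 (mitochondrially encoded mRNAs). Pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 3.79 to 17.3, so no library was counted as a duplicate.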

Results

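Gene expression was measured by RNA sequencing in HFF cells, an established culture of human foreskin fibroblasts, after irradiation with 40 mJ per cm2 of ultraviolet B (UVB), the band of sunlight that damages DNA directly. The 3 libraries of the UVB group came from irradiated cells kept in vehicle, and the 3 libraries of the UVB + sauchinone group came from irradiated cells given 10 µM sauchinone, a plant lignan, in culture for 48 h. The total count per library was 20984851, 22083818 and 23075536 in UVB replicates 1, 2 and 3, and 21645464, 23076388 and 22929719 in UVB + sauchinone replicates 1, 2 and 3. Between 24223 and 25259 genes had at least 1 count in a library, and 15704 genes had enough counts to be tested. At this depth 3 counts corresponded to 0.130 to 0.143 CPM in a library (CPM, the count scaled to a fixed library size), a floor that covers counting error only. Spearman correlations of the libraries lay between 0.991 and 0.994 within a group and between 0.964 and 0.975 across the groups. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All libraries carried the same batch label. Unirradiated cells were not analysed here, so each value below compares irradiated cells with and without the compound.

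The comparison asked how sauchinone altered gene expression in UVB-irradiated dermal fibroblasts. With sauchinone, 30 of 34 structural matrix genes and 24 of 30 genes of mitosis fell, and 21 of 25 immediate early genes, 21 of 28 antioxidant targets of NRF2, 17 of 26 ATF4 targets and 17 of 29 p53 targets rose. Each of these 6 lists passed camera with its preset correlation, and none passed with an estimated correlation (adjusted p = 0.20 to 0.30). COL3A1, which encodes a fibrillar collagen of skin, was 2.18-fold lower, at 1992 ± 24.7 CPM in UVB and 914 ± 38.4 CPM in UVB + sauchinone (mean ± SD, n = 3 in each group). FOS, a subunit of the transcription factor AP-1, was higher, at 1.51 ± 0.62 CPM and 22.7 ± 5.83 CPM. HMOX1, the haem-degrading enzyme induced by oxidative stress, was 2.93-fold higher, at 48.8 ± 3.96 CPM and 143 ± 7.81 CPM. CENPF, a kinetochore protein of dividing cells, was 3.15-fold lower, at 61.4 ± 10.8 CPM and 19.5 ± 3.08 CPM.

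In edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 7786 of the 15704 genes (49.6%) differed between the groups, 3872 of them higher and 3914 lower with sauchinone. The median absolute log2 fold change of these genes was 0.59, and 1815 of them changed at least 2-fold, 667 higher and 1148 lower. Every library of one group lay above every library of the other in 8963 genes (57.1%), against the 10% that chance gives with 3 libraries in each group. Genes with a long genomic span were lower more often. In the longest of 5 equal groups of genes, with spans of 88.7 to 2242 kb, 58.5% of genes were lower and 7.99% higher, and in the shortest, with spans of 0.062 to 6.93 kb, 8.12% were lower and 29.4% higher.

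Among the largest rises of genes with a mean of at least 1 CPM before TMM scaling were ARC, FOS, RASD1 and FOSB, each with a span under 7.19 kb. KPRP, an epidermal differentiation gene, had 3, 0 and 2 counts in UVB replicates 1, 2 and 3 and 31, 63 and 37 in UVB + sauchinone replicates 1, 2 and 3 (edgeR adjusted p = 7.7e-07), and no fold change is given because every UVB count is at or under the floor. ARC rose by 4.46 ± 0.31, and RASD1 and FOSB by 3.83 ± 0.27 and 3.83 ± 0.23 (log2 fold change ± SE). The 6 largest falls belonged to CHRM2, CD36, SYTL5, SLC38A11, NCKAP5 and POSTN. CHRM2, a muscarinic acetylcholine receptor gene on chromosome 7 at 136868652 to 137020255 (GRCh38, plus strand), had 292 counts over the UVB libraries and 2 over the UVB + sauchinone libraries, a ratio of 154 with a 95% counting interval of 42.3 to 1278. CD36, a fatty acid and scavenger receptor gene on chromosome 7 at 80369575 to 80679277, was lower, at 34.9 ± 4.47 CPM and 2.16 ± 0.87 CPM (n = 3; edgeR adjusted p = 1.6e-13), and its log2 fold change of −4.0 ± 0.18 became −3.15 when the trend with its span of 310 kb was removed. The log2 fold changes of SYTL5, SLC38A11 and POSTN, the gene of the matrix protein periostin, were −3.96 ± 0.37, −3.92 ± 0.25 and −3.62 ± 0.39. That of NCKAP5, which spans 897 kb, was −3.82 ± 0.48 and became −2.44 when the trend with span was removed. NCKAP5 had 46, 32 and 61 counts in UVB replicates 1, 2 and 3 and only 1, 3 and 6 in UVB + sauchinone replicates 1, 2 and 3. The size of its fall is therefore uncertain, as the lower counts lie near the floor.

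**Figure D1:**
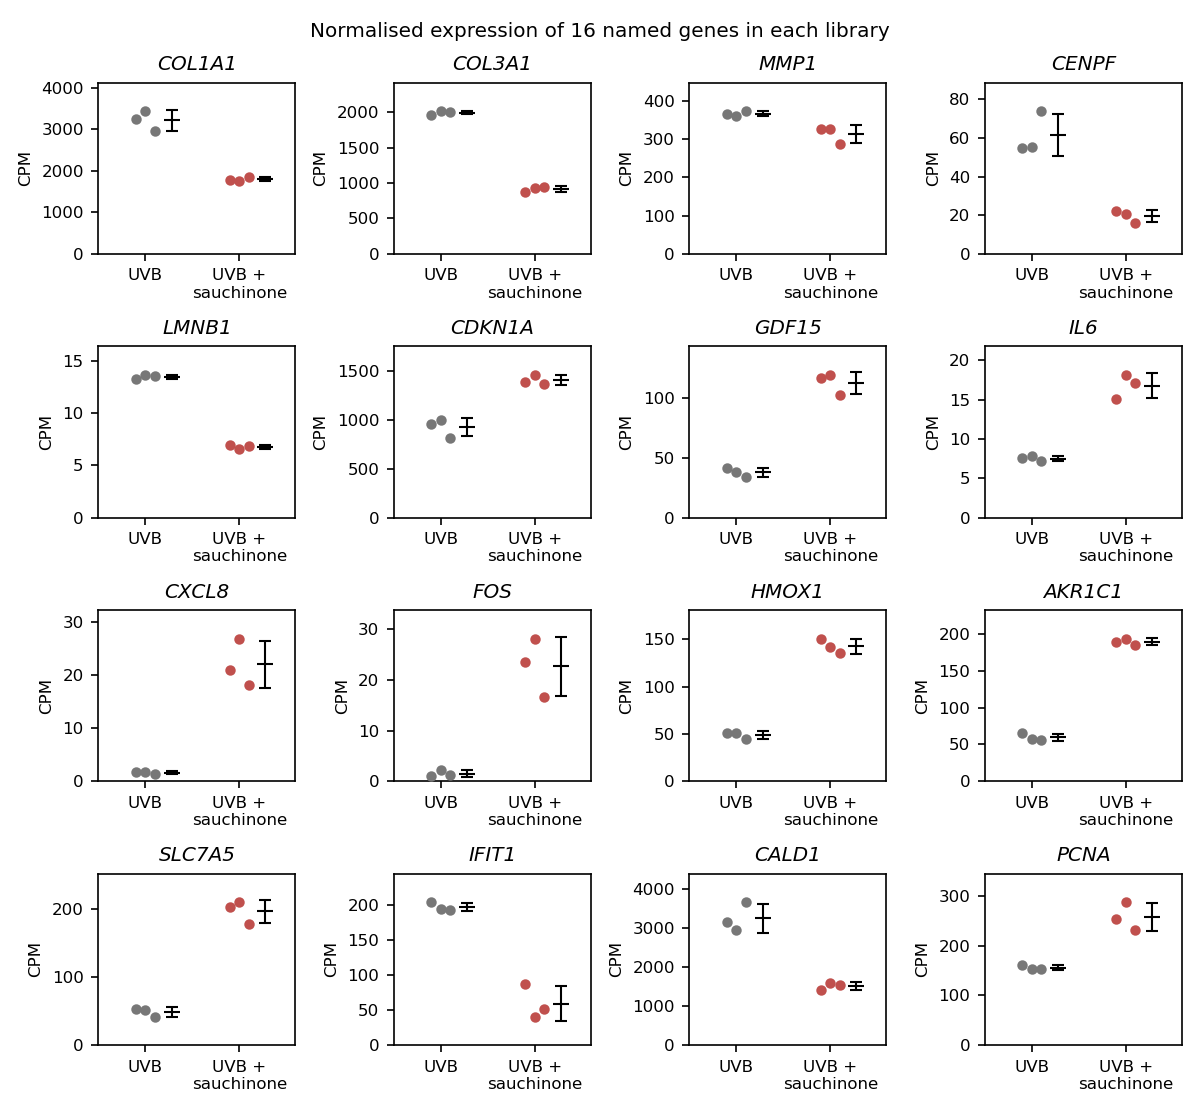
Normalised expression in CPM (y axis, from 0) of 16 named genes in each library of the UVB and UVB + sauchinone groups, with points for libraries and black bars for the mean ± SD of 3 libraries. The groups did not overlap in any of the 16 genes, and COL1A1, for example, was at 3217 ± 247 CPM in UVB and 1800 ± 47.1 CPM in UVB + sauchinone.

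Structural matrix genes fell as a group in camera with its preset correlation (adjusted p = 6.5e-10, and 0.20 with an estimated correlation). Of 34 measured members, 30 fell and none rose, both over all genes tested and when adjusted over the list alone (0 rose and 30 fell), and the median log2 fold change was −0.77. COL1A1, the gene of a type I collagen chain (ENSG00000108821, chromosome 17 at 50184101 to 50201632, minus strand, GRCh38), fell by 0.84 ± 0.066 on the log2 scale (SE; edgeR adjusted p = 6.3e-10). COL3A1 (ENSG00000168542, chromosome 2 at 188974373 to 189012746, plus strand) fell by 1.12 ± 0.063 (edgeR adjusted p = 2.8e-12). FBN2, a microfibril gene that spans 401 kb, fell by 1.54 ± 0.093, and by 0.57 when the trend with span was removed. The 4 members that did not pass, looked up after the test, were EFEMP1, MFAP5, SPARC and VCAN, with log2 fold changes of −0.13, 0.08, 0.04 and 0.0040. Members had a median span of 47.4 kb, and the list's median was lower than in each of 10000 random lists matched on span and mean expression.

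Genes of matrix proteases moved both ways. Of 22 measured members 7 rose, 7 fell and 8 did not pass, with the same counts when adjusted over the list alone, and the median log2 fold change was −0.067 (camera adjusted p = 0.81). MMP16, a membrane-type metalloproteinase gene, fell by 1.32 ± 0.13 on the log2 scale, and by 0.50 when the trend with its span of 296 kb was removed. FAP, a fibroblast surface protease gene, fell by 1.09 ± 0.12. MMP1, the interstitial collagenase gene (ENSG00000196611, chromosome 11 at 102789401 to 102798160, minus strand), was at 366 ± 6.60 CPM in UVB and 313 ± 23.4 CPM in UVB + sauchinone (n = 3), a log2 fold change of −0.22 ± 0.071 (edgeR adjusted p = 0.012). That call was lost without UVB + sauchinone replicate 3 (−0.16, edgeR adjusted p = 0.12) and when a trend with GC content was removed (−0.10, edgeR adjusted p = 0.15), while removing a trend with span or with exonic size gave −0.43 and −0.36, and the adjusted p ran from 2.9e-05 to 0.15 over all alternatives. Among the TGF-beta and myofibroblast genes 13 of 25 fell, 5 rose and 7 did not pass (13 and 6 when adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.052). The list passed without UVB replicate 3 (camera adjusted p = 0.018), without UVB + sauchinone replicate 3 (0.041) and when a trend with span, exonic size or GC content was removed (0.014, 0.026 and 0.0099). Over all alternatives its adjusted p ran from 0.0020, in the rotation test fry, to 0.35, in camera with an estimated correlation. CALD1, an actin-binding protein gene of contractile cells, fell by 1.10 ± 0.076, and by 0.43 when the trend with its span of 226 kb was removed. NOX4, an NADPH oxidase gene, fell by 2.34 ± 0.19. The 5 members that rose, named after their values were seen, were PMEPA1, SMAD7, TGFB1, CCN1 and SKIL, at 0.78, 0.58, 0.37, 0.25 and 0.25. PMEPA1, SMAD7 and SKIL are known as feedback inhibitors of TGF-beta signalling. Pericyte and smooth muscle markers, fixed as a control for another cell type, moved in the same direction as the matrix genes, with 5 of 8 lower and none higher (5 and 0 when adjusted over the list alone) and a median of −0.74 (camera adjusted p = 0.011, and 0.20 with an estimated correlation). These 5, named after their values were seen, were LMOD1, RGS5, ABCC9, CSPG4 and NOTCH3, with log2 fold changes of −1.93, −2.58, −0.93, −0.79 and −0.70.

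Immediate early genes, which respond to growth factor and stress signals, rose as a group. Of 25 measured members 21 rose, none fell and 4 did not pass (21 and 0 when adjusted over the list alone), and the median log2 fold change was 0.78 (camera adjusted p = 2.3e-08, and 0.20 with an estimated correlation). FOS (ENSG00000170345, chromosome 14 at 75278826 to 75282230, plus strand) rose by 3.91 ± 0.22 (SE; edgeR adjusted p = 3.1e-12), and IER3, a stress-response gene, rose by 1.92 ± 0.11. Members had a median span of 5.82 kb, and the list's median exceeded that of each of 10000 random lists matched on span and mean expression.

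Of 22 genes of the inflammatory secretome 13 rose, 4 fell and 5 did not pass (13 and 4 when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.0062, and 0.24 with an estimated correlation). CXCL8, the neutrophil chemokine gene (ENSG00000169429, chromosome 4 at 73740519 to 73743716, plus strand), rose 13.7-fold, from 1.61 ± 0.25 CPM to 22.0 ± 4.42 CPM (n = 3; edgeR adjusted p = 3.5e-13). IL11, a cytokine gene of stromal cells, rose by 2.54 ± 0.13 on the log2 scale, and IL6 rose 2.24-fold, from 7.5 ± 0.32 CPM to 16.8 ± 1.57 CPM (edgeR adjusted p = 1.1e-07). The 4 that fell, named after their values were seen, were CCL2, CSF1, IL33 and ICAM1, with log2 fold changes of −0.62, −0.49, −0.53 and −0.35. CCL2, a monocyte chemokine gene, had the highest level of these 4, at 106 CPM in UVB and 69.2 CPM in UVB + sauchinone.

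Antioxidant and detoxification genes induced by NRF2 rose in 21 of 28 members, with 3 lower and 4 that did not pass (21 and 3 when adjusted over the list alone), and the median log2 fold change was 0.64 (camera adjusted p = 7.4e-06, and 0.20 with an estimated correlation). HMOX1 (ENSG00000100292, chromosome 22 at 35380361 to 35394214, plus strand) rose by 1.55 ± 0.085 (edgeR adjusted p = 2.0e-12). AKR1C1, an aldo-keto reductase gene, rose by 1.67 ± 0.081, a value left uncertain by the similar sequence of its paralogs. The 3 lower members, named after their values were seen, were ME1, ABCC1 and AKR1C3, at −0.76, −0.46 and −0.25. Among ATF4 targets, the genes of the integrated stress response, 17 of 26 rose, 1 fell and 8 did not pass (17 and 1 when adjusted over the list alone), with a median of 0.50 (camera adjusted p = 1.3e-05, and 0.24 with an estimated correlation). SLC7A5 and SLC3A2, which encode the light and heavy chains of an amino acid transporter, rose 4.04-fold and 3.72-fold, by 2.01 ± 0.097 and 1.90 ± 0.086 on the log2 scale. The member that fell, named after its value was seen, was ALDH1L2, a mitochondrial folate enzyme gene, at −0.50.

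Of 29 p53 targets 17 rose, 4 fell and 8 did not pass (18 and 4 when adjusted over the list alone), and the median log2 fold change was 0.47 (camera adjusted p = 0.00057, and 0.30 with an estimated correlation). GDF15, a secreted stress cytokine gene, rose by 1.58 ± 0.093, and SESN2, a stress-induced regulator of growth signalling, by 1.52 ± 0.12. CDKN1A, the gene of the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6 at 36676460 to 36687337, plus strand), rose 1.52-fold, from 926 ± 93.6 CPM to 1406 ± 50.1 CPM (n = 3; edgeR adjusted p = 3.9e-07). The 4 that fell, named after their values were seen, were SPATA18, CCNG1, ZMAT3 and TIGAR, at −0.60, −0.24, −0.22 and −0.23. Genes of endoplasmic reticulum chaperones rose in 10 of 20 members and fell in 3 (11 and 3 when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.044, and 0.63 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response, rose by 0.88 ± 0.081 and HSPA5, the main chaperone of that compartment, by 0.67 ± 0.071. The 3 that fell, named after their values were seen, were SEL1L, HSP90B1 and PDIA6, at −0.34, −0.33 and −0.20. This list's call was lost without UVB replicate 1 (camera adjusted p = 0.060), without UVB + sauchinone replicate 2 (0.077), with upper-quartile normalization (0.0504) and when the trend with span was removed (0.19). Over all alternatives its adjusted p ran from 0.0090, in the rotation test fry, to 0.63, in camera with an estimated correlation. Heat shock genes rose in 10 of 20 members, with DNAJB4 lower at −0.67 and 9 that did not pass (10 and 1 when adjusted over the list alone). Their median was 0.29 (camera adjusted p = 0.010, 0.30 with an estimated correlation and 0.085 when the trend with span was removed). The lowest adjusted p over the alternatives, 0.0013, came from the rotation test fry and not from camera. HSPB8, a small heat shock protein gene, rose by 1.06 ± 0.084, and HSPA1B by 1.45 ± 0.11, a value left uncertain by reads shared with its near-identical neighbour HSPA1A.

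Genes of mitosis fell as a group. Of 30 measured members 24 fell, none rose and 6 did not pass (25 and 0 when adjusted over the list alone), and the median log2 fold change was −0.82 (camera adjusted p = 4.5e-08, and 0.24 with an estimated correlation). CENPF (ENSG00000117724, chromosome 1 at 214603195 to 214664571, plus strand) fell by 1.65 ± 0.12 (SE; edgeR adjusted p = 2.4e-10), and CENPE, a kinetochore motor gene, by 1.65 ± 0.13. LMNB1, the lamin B1 gene whose loss is a readout of senescence, was 1.99-fold lower, at 13.5 ± 0.22 CPM in UVB and 6.77 ± 0.18 CPM in UVB + sauchinone (n = 3; edgeR adjusted p = 1.3e-06). DNA replication genes moved both ways, with 7 of 29 higher, 12 lower and 10 that did not pass (7 and 12 when adjusted over the list alone), and a median of −0.14 (camera adjusted p = 0.63). PCNA, the sliding clamp gene, rose by 0.72 ± 0.08, while POLA1, the catalytic subunit gene of DNA polymerase alpha, fell by 1.86 ± 0.17, and by 1.02 when the trend with its span of 303 kb was removed. DNA repair genes fell in 15 of 28 members and rose in 1, ERCC3, at 0.35, and 12 did not pass (16 and 1 when adjusted over the list alone). Their median was −0.34 (camera adjusted p = 0.0043, and 0.20 with an estimated correlation). FANCD2 and FANCI, partners in the repair of DNA crosslinks, fell by 1.89 ± 0.18 and 1.23 ± 0.096. Replication-dependent histones, fixed as a control for RNA without a poly(A) tail, moved opposite to the mitotic genes. Of 18 measured members 14 rose and none fell (17 and 0 when adjusted over the list alone), with a median of 0.96 (camera adjusted p = 4.6e-06, and 0.20 with an estimated correlation). Single histone genes are uncertain, since their near-identical copies can share reads.

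Interferon-stimulated genes fell in 11 of 24 members, rose in 2 and did not pass in 11 (11 and 2 when adjusted over the list alone), with a median log2 fold change of −0.51 (camera adjusted p = 0.024, and 0.70 with an estimated correlation). IFIT1 and IFIT2, which encode antiviral RNA-binding proteins, fell by 1.74 ± 0.16 and 1.15 ± 0.092. The 2 that rose, named after their values were seen, were IRF7 at 1.5 and ISG15 at 0.48. The list's call was lost without UVB replicate 1 (camera adjusted p = 0.060) and without UVB + sauchinone replicate 2 (0.075), within a range of 0.0015 to 0.70 over all alternatives.

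The metabolic lists did not pass camera with all 6 libraries, and single members moved both ways. Cholesterol synthesis genes rose in 3 and fell in 7 of 23 members, with the same counts when adjusted over the list alone, and had a median of −0.038 (camera adjusted p = 0.73). SQLE, a rate-controlling enzyme gene, rose by 0.66 ± 0.082, and NSDHL, named after its value was seen, rose by 0.37. Hypoxia and glycolysis genes rose in 13 and fell in 5 of 26 members, with the same counts when adjusted over the list alone, and had a median of 0.33 (camera adjusted p = 0.066). This list passed without UVB replicate 2 (camera adjusted p = 0.029), within a range of 0.029 to 0.73 over all alternatives. PFKFB3, a regulator of glycolysis, rose by 0.89 ± 0.097 and TPI1, a glycolytic enzyme gene, by 0.77 ± 0.08, and the 5 that fell, named after their values were seen, were PDK1, LDHA, P4HA1, HK2 and PFKP, at −0.72, −0.32, −0.30, −0.29 and −0.33. Nuclear genes of oxidative phosphorylation rose in 9 and fell in 5 of 35 members, with the same counts when adjusted over the list alone and a median of 0.065 (camera adjusted p = 0.63). ATP5F1B rose by 0.53 ± 0.071, and by 0.32 when the trend with span, 7.81 kb for this gene, was removed, and NDUFB5 fell by 0.42 ± 0.083, and by 0.23 when a trend with GC content was removed. Autophagy and lysosome genes rose in 8 and fell in 7 of 31 members, with the same counts when adjusted over the list alone and a median of 0.039 (camera adjusted p = 0.47), and SQSTM1 and MAP1LC3B, which encode an autophagy receptor and an autophagosome protein, rose by 1.33 ± 0.071 and 0.73 ± 0.074. Of 6 genes linked to the aryl hydrocarbon receptor, TIPARP and CYP1A1 rose, by 0.38 ± 0.071 and 1.26, AHRR fell by 0.66 and SERPINB2 by 0.25 ± 0.068, and 2 did not pass, with the same calls when adjusted over the list alone, CYP1A1 and AHRR being named after their values were seen. The SERPINB2 call was lost when a trend with GC content was removed (−0.096, edgeR adjusted p = 0.24), removing a trend with exonic size gave −0.39, and the adjusted p ran from 3.0e-05 to 0.24 over all alternatives. The median of these 6 genes was −0.00025, their mean was 0.12 and the test pointed upward (camera adjusted p = 0.76).

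**Figure D2:**
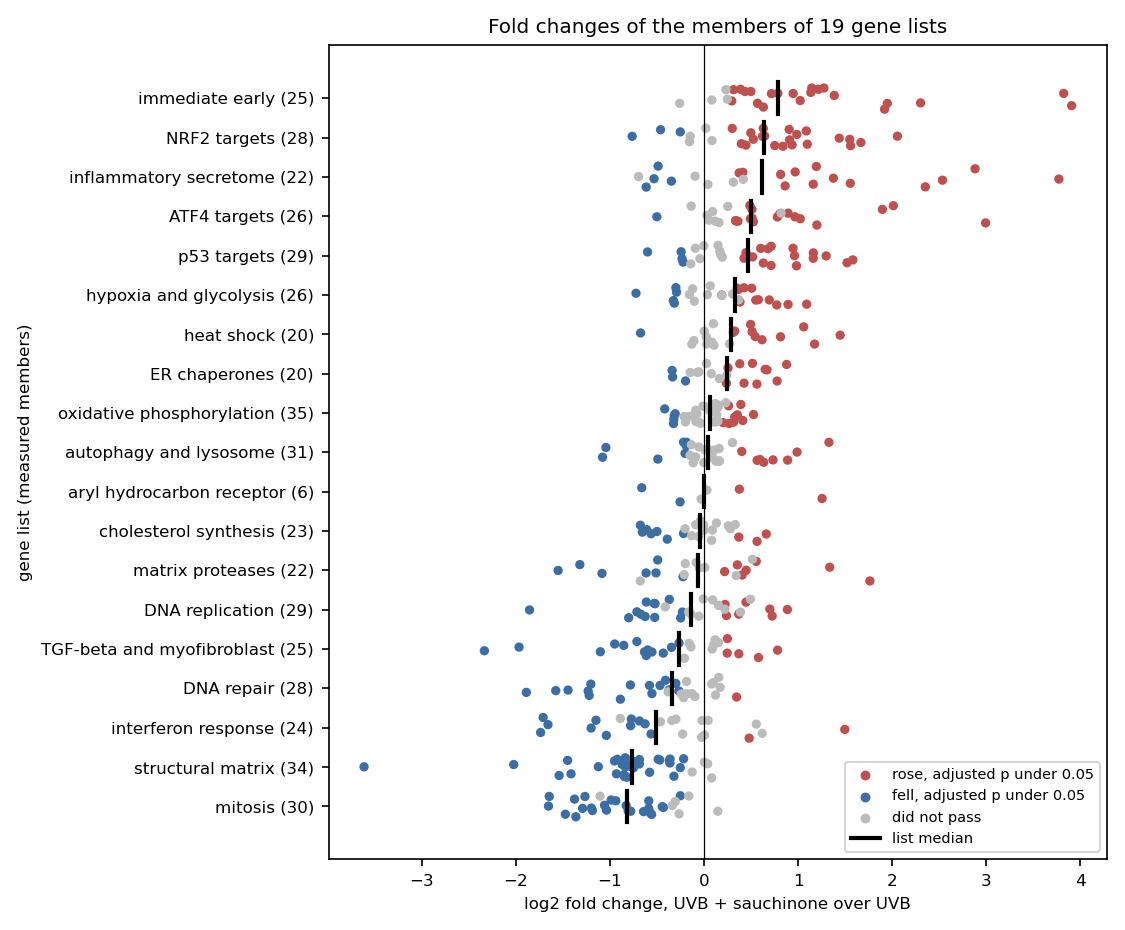
Log2 fold change of UVB + sauchinone over UVB (x axis) for the measured members of the 19 biological gene lists (y axis, number of measured members in parentheses). Points are genes, red where they rose and blue where they fell at an edgeR adjusted p under 0.05 and grey where they did not pass, and black lines are list medians, which run from −0.82 for mitosis to 0.78 for immediate early genes.

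Markers of other cell types and measures of RNA content were compared in the same way. Keratinocyte markers had a median of 0.11 over 7 measured members (camera adjusted p = 0.73), with SFN, also a p53-induced cell cycle regulator, higher (no fold change is given, as its mean of 0.091 ± 0.042 CPM with UVB alone is under the floor) and DSP and KRT15 lower, at −0.41 and −0.76. Melanocyte markers fell in 3 of 5 members, MITF and MLANA among them, with a list median of −0.44 (camera adjusted p = 0.14). Of 3 endothelial markers TEK fell by 1.47, and the list had a median of 0.29, a mean of −0.011 and a test that pointed downward (camera adjusted p = 0.85). Of 6 immune markers CD74 rose by 0.87, and the list had a median of 0.74 (camera adjusted p = 0.098). Adjusted over the list alone CD74 did not pass, and the calls of the keratinocyte, melanocyte and endothelial lists were the same. These members were named after their values were seen. Ribosomal protein genes rose in 48 of 76 members and fell in RPL3 alone, at −0.30 (49 and 1 when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 4.6e-06, 0.70 with an estimated correlation and 0.42 when the trend with span was removed, with a lowest value of 1.3e-08 over the alternatives). Mitochondrially encoded mRNAs fell in 9 of 13 members and rose in 2, MT-ND1 and MT-ND2, at 0.42 and 0.20 (9 and 2 when adjusted over the list alone), with a median of −0.28 (camera adjusted p = 0.091). This list passed without UVB + sauchinone replicate 3 (camera adjusted p = 0.041) and when a trend with span or exonic size was removed (0.0041 and 0.023), within a range of 0.0041 to 0.79 over all alternatives. The mitochondrial ribosomal RNAs took a larger share of counts with sauchinone, at 0.174% ± 0.0045 and 0.412% ± 0.033 for MT-RNR1 and 1.26% ± 0.043 and 1.85% ± 0.13 for MT-RNR2 (SD, n = 3). Protein-coding genes took 97.0% ± 0.10 of counts in UVB and 96.2% ± 0.17 in UVB + sauchinone. Across all 27 lists, 14 passed camera with its preset correlation, 9 upward and 5 downward. With an estimated correlation none passed, although 6 had an unadjusted p under 0.05, and for each of the 14 this was the highest adjusted p over all alternatives run. The rotation test fry, which asks only whether a list's genes move one way on balance, called 20.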

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

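The trend removals were chosen after the data were seen, and the other alternatives before. The count of changed genes (7786) stayed within 1.5 times under DESeq2 (7108), RLE and upper-quartile scaling (7786 and 7757), no filter and a stricter filter (7685 and 7470), limma-voom (7793) and removal of trends with span, exonic size and GC content (7271, 7786 and 8232). A minimum of 2-fold left 1815 genes, 667 higher and 1148 lower, by its construction. Leaving out each library in turn gave 6718 to 7914 changed, 3296 to 3937 higher and 3422 to 3977 lower genes, and 12 to 16 lists. With the span trend removed, 5712 of the 7786 calls remained in the same direction and 163 were called in the opposite direction. Same-numbered libraries had correlations of deviations of 0.0072, −0.078 and −0.031, so no pairing by number was seen. A shared culture or day is not excluded by this, and the labels do not state one. With the replicate number as a block 7280 genes changed and 14 lists passed. The 14 list calls became 0 with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 20. For DNA repair and for pericyte and smooth muscle markers the estimates, −0.0015 and −0.044, lay below the preset 0.01. Their unadjusted camera p still rose, from 0.0014 to 0.023 and from 0.0048 to 0.043. A higher correlation between genes thus does not account for the change in these lists, and the cause was not tested. The list calls were 14 with RLE scaling and with the stricter filter, 13 with upper-quartile scaling and 13, 16 and 15 with the span, exonic size and GC trends removed. Calls were lost for the chaperone, interferon, heat shock and ribosomal protein lists as given in the report, and gained, as given there, for the TGF-beta and myofibroblast, hypoxia and glycolysis, and mitochondrially encoded mRNA lists. With fry the TGF-beta and myofibroblast, hypoxia and glycolysis, autophagy and lysosome, aryl hydrocarbon receptor, melanocyte and immune lists gained one (adjusted p = 0.0020, 0.048, 0.032, 0.018, 0.0022 and 0.0021). Of the values of named genes under all alternatives 861 kept their direction and call and 3 lost the call, those of MMP1 and SERPINB2, and none changed sign. Depth sets the floor of 0.130 to 0.143 CPM for 3 counts in a library.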

Other observations

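Gene Ontology enrichment, tests of elongation, of S phase and of transcript length over the 4 upper exonic size groups, and the lists used below were chosen after the results were seen. Among the 433 annotated genes at least 2-fold higher with sauchinone, 14 of 1921 biological process terms were enriched. Chemokine-mediated signalling held 6 of its 11 genes, CXCL1, CXCL2, CXCL3, CXCL6, CXCL8 and CCL26, against 0.397 by chance (Fisher's exact test, adjusted p = 0.0016). The members of the term had a median span of 2.38 kb. In UVB, CXCL1, CXCL3 and CXCL6 averaged only 0.99, 0.29 and 0.81 CPM, and CXCL2, at 0.11 CPM, was under the floor. The CXCL genes named lie close together on chromosome 4, while the test treats genes as independent. Response to cAMP held 9 of 35, FOS, FOSB, AREG, THBD, PER1 and DUSP1 among them (adjusted p = 0.0028). Natural killer cell activation held 4 of 10 (adjusted p = 0.044), which were IL21R and the stress-ligand genes ULBP1, ULBP2 and ULBP3. Cellular response to oxidative stress held 10 of 68 (adjusted p = 0.044), with SRXN1, SLC7A11 and SESN2 among them.

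Among the 849 annotated genes at least 2-fold lower, 10 terms were enriched. Extracellular matrix organization held 24 of 100 genes against 7.07 by chance (Fisher's exact test, adjusted p = 0.00015), including POSTN, COL10A1, COL11A1, COL15A1, ADAMTS2 and ADAMTS12, and the members of the term had a median span of 49.7 kb. Calcium ion transport held 12 of 37 (adjusted p = 0.0035), including the channel genes CACNA1C, TRPC4, ITPR1 and ITPR2, and its members had a median span of 70.6 kb. Synaptic transmission held 21 of 102 (adjusted p = 0.0035), including GRIA1, NLGN1, NRXN3 and KCNMA1, and its members had a median span of 49.3 kb. The enrichment test was not matched on span. Among genes abundant in fibroblasts outside the matrix list, CAV1, PRRX1, TIMP3, PDGFRB, PDGFRA and VIM fell and TIMP1, S100A11, S100A10, LGALS1, S100A6, TWIST1 and CD63 rose, with 7 of 20 that did not pass.

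Genes with a longer genomic span had lower log2 fold changes, with medians of 0.20, 0.17, 0.067, −0.069 and −0.44 from the shortest to the longest of 5 groups and a Spearman correlation of −0.385 across genes, which are not independent replicates. GC content is argued against as the whole cause, since the weakest correlation with span within 5 groups of GC content was −0.223. Transcript length was not decided over the 5 groups of exonic size. For the shortest group of exonic size the correlation was −0.0965, too close to the bound of −0.1 set for the test to decide. In the 4 upper groups the weakest was −0.291, so the trend was present there among genes of like exonic size. Those 4 were taken apart after these values were known, so this is no separate test. Exonic size was also compared within 5 groups of span, from the shortest to the longest. Its correlation with log2 fold change was 0.094, 0.044, 0.037, 0.0042 and −0.066, with no bound set beforehand. A fall set by transcript length would make each of these negative. They argue against it as the whole cause in the 4 shorter groups of span, and the longest was only weakly negative. Less transcription elongation through long genes with sauchinone was not decided by any value here. The correlation among members of the biological lists, −0.426, restates the trend on part of the same genes, and with counts over all exons, elongation and other steps cannot be told apart.

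Replication-dependent histone mRNAs rose while mitotic mRNAs fell. The short span of histone genes is argued against, since their median was 0.827 after the span trend was removed (95% bootstrap interval 0.570 to 1.18). More cells in S phase was not decided. The upper quartile of DNA replication genes, 0.239, lay below the lower quartile of the histones, 0.718, but the 2 kinds of gene need not change by like amounts. Of 29 DNA replication genes 7 rose and 12 fell, with a median of −0.14, and of −0.15 after the span trend was removed. More RNA without a poly(A) tail kept in the sauchinone libraries may account for the rise: 4 of 6 measured RNAs of that kind were higher, none was lower and their median was 0.697. Those 4 were MT-RNR1, MT-RNR2, RN7SL1 and SNORD3A, at 1.2, 0.51, 0.88 and 1.51. The median of the 6 lay only just above the 95% range of medians of matched random lists, −0.350 to 0.696. MT-RNR1 and MT-RNR2 are mitochondrial ribosomal RNAs, so outside the mitochondria the rise rested on RN7SL1 and SNORD3A. The mitochondrial mRNAs MT-ND1 and MT-ND2 also rose, while 9 of 13 such mRNAs fell. Whether a change of mitochondrial RNA lay behind these rises was not tested. An effect of sauchinone on histone mRNA itself was not tested and stays open.

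The fall of structural matrix genes is argued against as part of the span trend, since its median lay at percentile 0 of the matched lists. The median of 20 abundant fibroblast genes was 0.0326 (95% bootstrap interval −0.202 to 0.205), with 7 higher and 6 lower, so abundant genes did not all fall alike. This does not decide on a lower share of fibroblast RNA, since these genes were not picked as particular to fibroblasts. An effect of sauchinone on matrix mRNA is a hypothesis found and tested on the same data, and differences in cell density or in the culture of the groups were not tested.

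The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each count below 1 of 10 splits, the real one, reached the real value. The real split gave 7786 changed, 3872 higher and 3914 lower genes, and the highest other split gave 0 in edgeR for each of these counts, with 272 genes at an unadjusted p under 0.05 and 0 in limma-voom. Every other split put libraries of both groups on each side, so a difference between the groups counted as spread within a side. Few genes could be called there, so these counts do not show what chance alone gives. For gene lists the real split gave 14 and the highest other split 11. The gene ENSG00000280614 had 600 counts in UVB replicate 1 and 10 to 82 in the other 5 libraries.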
